A study of Homo sapiens with 3 samples.

How the data were processed

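Hi-C, which records the frequency with which pairs of genomic sites are ligated together in crosslinked nuclei, was performed on 3 samples of HCT116, a human colorectal carcinoma cell line, all in a p53-null background. Per the labels, 1 library was the parental line (called wild-type), 1 was a clone carrying a CRISPR/Cas9 deletion of ORC2, and 1 was a clone in which ORC2 had been put back from a vector. Chromatin was cut with DpnII, the ends were filled in with biotinylated nucleotide, and ligated fragments were captured on streptavidin beads, per the labels' protocols. ORC2 is a subunit of the origin recognition complex, which marks sites where DNA replication can start.

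The file used is a list of 279669 chromatin loops deposited by the authors, with a left end, a right end and a class word for each loop. Its positions are in hg38 per the file's name. The submitters' processing notes name Bowtie and the builds hg19 and hg38 without giving their roles. The loop caller, the contact normalisation, the thresholds, the samples that were compared and the meaning of the word conserved in the classes are not given in the sources used here. The class words are the authors' own comparison. Per its name the file lists changed loops, so loops classed as not conserved are not taken as unchanged. The classes read conserved gain, conserved lost and not conserved, and the loops are called gained, lost and not conserved below. Which sample a gain or a loss refers to is therefore not known, and no direction is drawn from the classes with respect to ORC2. The list carries no loop strength, no read depth and no replicate values, so depth is unknown and no error between libraries could be computed. Whether contacts were corrected for coverage is not given either, and without such a correction a difference in copy number between clones would enter the classes.

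The class field held a fragment of a number in place of a class word in 49 rows, and these were left out. A further 2 rows repeated another row and were dropped, which left 279618 loops. Left ends lay 1 base after another loop's right end at 11951 of 53029 distinct left ends, so positions were read as counted from 1 with both ends included. Each loop end was read as 5 kb inward from the listed position. Neighbouring ends lay 4760 bp apart at the median, over gaps under 10000 bp. That ceiling was set from the 5 kb width, so the median does not establish the width. A compartment table was also supplied. Its 6 columns of per-sample values carry only the names S1, S2 and S3, which match no label of any sample, so these columns were not used and the planned compartment comparisons were not made.

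Neighbouring loops of a class were joined into regions where both of their ends lay within 10 kb of another loop's ends. Protein-coding genes came from the RefSeq annotation of GRCh38.p14, the assembly that hg38 names. That table gives gene bodies without strand or exons, so a gene was counted at a loop end when its body overlapped the 5 kb end, and whether an end lay in an exon, intron or UTR was not determined. Shares carry 95% Wilson intervals, which cover counting error only and treat loops as independent. Because neighbouring loops are not independent, intervals were also made by resampling 1 Mb windows of the genome 2000 times. These are the intervals given unless Wilson or another source is named. No interval covers differences between cultures or libraries. Where a count was 0, the limit given is the one 3 counts would make, which also treats loops as independent.

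The gene lists were fixed before the data were examined. For each list, the number of members at a gained or a lost end was set against 10000 random lists of the same size, drawn from genes at any listed loop end and matched in 10 groups on the number of listed loops. Percentiles from these lists describe this loop list and are not tests of the conditions. In a test of the gene-list step on simulated data over 9909 genes, 1.5% of unrelated lists fell in the top 2.5% of random lists. A list planted with many more changed genes than the background reached the 100th percentile, so weaker signals were not tested. The changed genes were placed at random there, so changed genes that cluster along the genome were not modelled. Joining recovered 200 of 200 simulated regions, and intervals from resampling covered the true share in 98% of simulated sets. Those sets held independent values, so coverage for clustered loops was not tested. The rule for naming loops planned before the data were examined needed loop strengths. It was replaced, after the file was seen, by the 10 regions with most loops in each class, the genes of the fixed lists and genes with many gained or lost loops. The ORC2 locus was always to be reported. Some genes that met these rules are not reported here.

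Alternatives were autosomes only, joining loops into regions at other distances, leaving out loops shorter than 100 kb, leaving out the 500 kb windows with most gained or lost loops (the 10 densest in gained and the 10 densest in lost loops, 19 windows in all), reading ends 10 kb inward, and matching random lists on gene length. Values were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.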

Results

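To look for changes of chromosome structure that depend on ORC2, Hi-C libraries were made from wild-type, ORC2-deleted and ORC2-rescued HCT116 cells, with 1 library in each group. The authors' deposited table listed 279618 loops with a readable class, from 6.28 kb to 1.99 Mb long, on 22 autosomes and chromosome X. Without replicate libraries, none of the values below has an error between cultures, and no test between the conditions was possible. The table does not name the samples behind a gain or a loss.

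Gained loops outnumbered lost loops by 10.0 to 1. In the authors' deposited table, the gained class held 5493 loops and the lost class 548, which is 1.96% (1.71 to 2.26%) and 0.196% (0.135 to 0.273%) of the listed loops. The remaining 273577 loops were classed as not conserved. Neighbouring loops fell into 1337 gained and 133 lost regions, a ratio of 10.1 to 1. Gained loops made up 90.9% (87.8 to 93.8%) of the gained and lost loops together. Lost loops lay in 114 windows of 500 kb and gained loops in 881, so the shares held by the 10 fullest windows of each class, 48.0% and 16.1%, are not comparable. Without these 19 distinct windows, 4601 gained and 285 lost loops were left.

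In the authors' deposited table, gained loops were longer than loops that were not conserved. Their median length was 300 kb (258 to 345 kb), against 222 kb (157 to 266 kb) for lost loops and 233 kb (221 to 246 kb) for loops that were not conserved. The interval of the gained median lay above that of the not conserved loops, whereas the interval of the lost median overlapped both. On 19 of 23 chromosomes the gained median exceeded the not conserved one. It was lower on chromosomes 13 (51.2 against 320 kb), 14 (218 against 262 kb), 17 (116 against 179 kb) and 22 (72.0 against 83.4 kb). Among loops of 100 to 250 kb, 1.34% (1.08 to 1.63%) were gained, and this share was 3.57% (2.84 to 4.38%) at 500 to 1000 kb and 11.0% (6.66 to 17.1%) above 1 Mb, where 261 of 2363 loops were gained. No lost loop was longer than 1 Mb, which allows a share of up to 0.127% if loops are independent (Wilson upper limit 0.162%). Lost loops cluster, so both limits are too tight. Loops up to 50 kb were gained in 2.37% of cases (0.989 to 4.36%). Without the 19 windows above this was 0.892% (0.515 to 1.42%), and the shares at 50 to 100 kb and 100 to 250 kb were 0.988% and 1.19%. These windows held no loop above 1 Mb, so leaving them out could not change the share of 11.0% there.

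**Figure D1:**
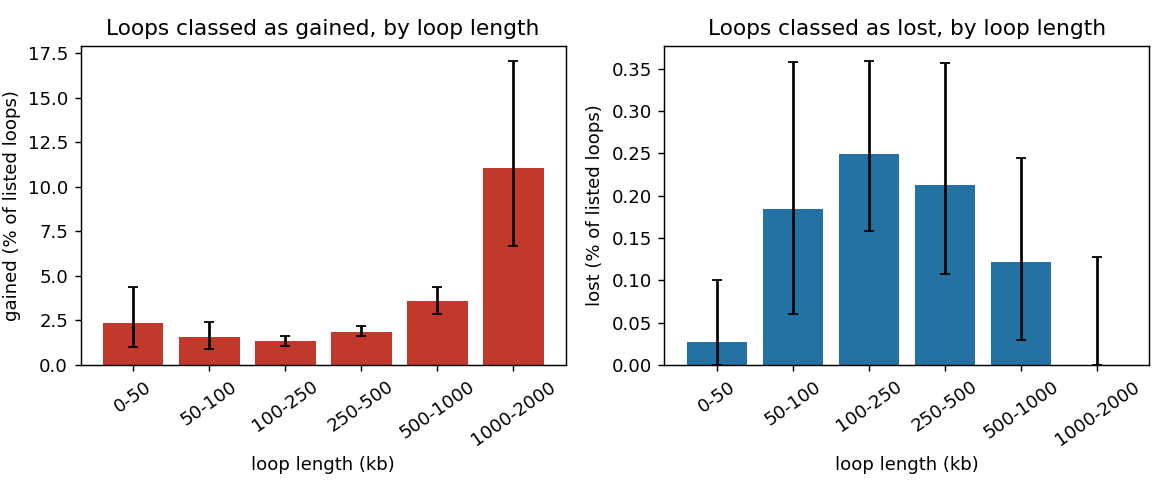
Percent of listed loops classed as gained (left) and lost (right) against loop length in kb, over the 279618 loops of the authors' deposited table, which names no samples. Bars are shares on separate linear axes from 0, and error bars are 95% intervals from resampling 1 Mb windows. For the length class with 0 lost loops the error bar gives the limit of 0.127% that 3 counts make if loops are independent. The gained share is highest above 1 Mb, at 11.0%.

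In the authors' deposited table, gained loops outnumbered lost ones on 22 of 23 chromosomes, the exception being X. Chromosome X had 79 lost and 9 gained loops. Its lost share of 2.28% (0.812 to 3.30%) compared with 0.170% (0.111 to 0.239%) on the autosomes, so that X held 1.24% of listed loops but 14.4% of lost ones. Of the 79 lost loops on X, 60 started past 150 Mb, near the end of the long arm, where 1539 of the 3469 listed loops of X (44.4%) also started. That position was chosen after the lost loops were seen there, so leaving out loops past it lowers the lost share by construction. Without them the lost share on X was 0.984% (0.0856 to 1.93%), from 4 regions, an interval that includes the autosomal share. It was 1.36% without the 19 windows above. Ends of lost loops on X lay at SSR4, a subunit of the endoplasmic reticulum translocon complex (27 of 75 listed loops lost), and IDH3G, a subunit of mitochondrial isocitrate dehydrogenase (18 of 69). Others lay at FLNA, which encodes the actin crosslinker filamin A (13 of 189), and HCFC1, a transcriptional cofactor (11 of 156). Chromosome 13 had 357 gained loops, 8.87% of those listed there, and 0 lost of 4027. Its resampling interval of 2.12 to 17.8% overlapped that of the genome-wide gained share (1.71 to 2.26%) but lay above the share itself, 1.96%. Without its densest windows the gained share on chromosome 13 was 3.09%. The lowest gained share on an autosome was 0.535%, on chromosome 19.

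**Figure D2:**
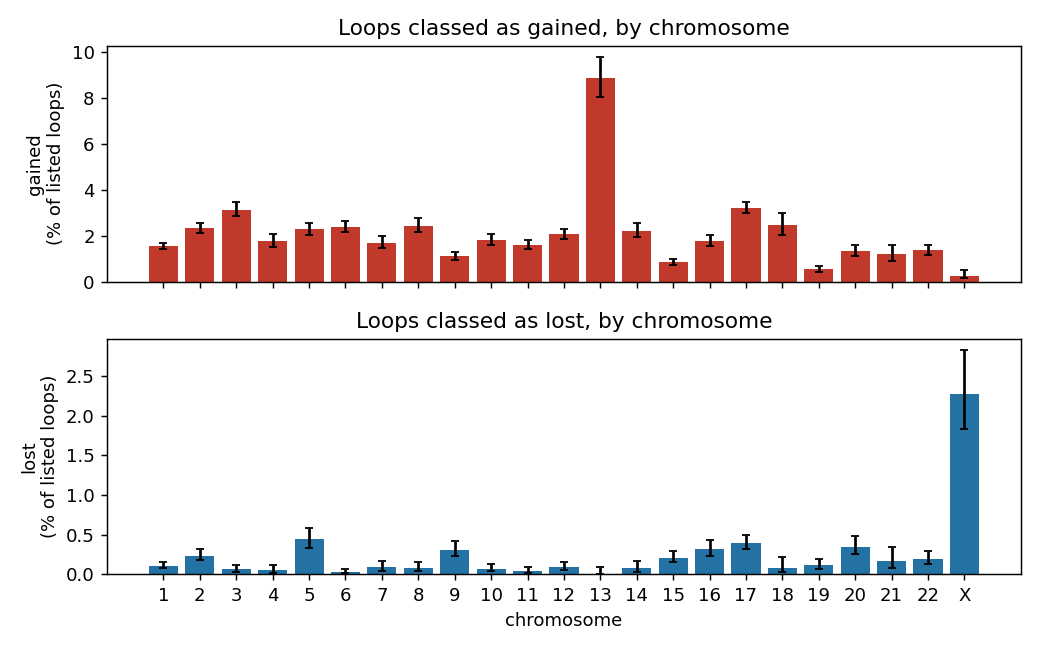
Percent of listed loops classed as gained (top) and lost (bottom) on each chromosome, on linear axes from 0. Error bars are 95% Wilson intervals and cover counting error only. Chromosome 13 has the highest gained share, 8.87%, and chromosome X the highest lost share, 2.28%.

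In the authors' deposited table, the 10 gained regions with most loops held either only loops of at least 159 kb or only loops of at most 112 kb. The longest-range of the 10 largest lay on chromosome 17 at 66186529 to 66917129, with 44 gained loops of 670 to 721 kb. Of these, 27 had an end at CACNG5, a calcium channel subunit gene, 11 at CEP112, a centrosomal protein gene, and 7 at APOH, encoding apolipoprotein H. On chromosome 16 at 84728569 to 84991891, 74 gained loops of 159 to 245 kb had ends at the deubiquitinase gene USP10 (56 loops) and at ZDHHC7 (10 loops), a palmitoyltransferase gene. On chromosome 3 at 133918010 to 134228921, 37 gained loops had an end at RYK, which encodes a Wnt-binding receptor, and 21 of them had the other end at the prostaglandin transporter gene SLCO2A1. Here 51 of the 73 listed loops inside the region were gained and 0 were lost. On chromosome 2 at 10423443 to 10687118, 32 gained loops had ends at NOL10, and 18 of them at ODC1, which encodes the first enzyme of polyamine synthesis. On chromosome 12 at 46660777 to 47029758, 33 gained loops had no protein-coding gene at either end.

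Short blocks made up 5 of the 10 largest gained regions, with loops from 7.11 to 9.78 kb upward. The largest, on chromosome 17 at 34456388 to 34708424, held 199 gained loops of at most 112 kb, of which 123 had an end in TMEM132E, a transmembrane protein gene linked to hearing. Overlapping blocks in ATP8A2, a phospholipid flippase gene on chromosome 13, held 42 and 40 gained loops, and counting all lengths 176 of the 272 listed loops at ATP8A2 were gained. A block of 43 gained loops lay at the alpha-tubulin gene TUBA3C on chromosome 13 (19120798 to 19200289). TUBA3C has near-identical copies elsewhere in the genome, so its contacts are reported as uncertain. The fifth block, on chromosome 22 at 34929593 to 34985161, held 33 gained loops and no protein-coding gene at its loop ends.

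The largest lost region overlapped the largest gained one. On chromosome 17 at 34558566 to 34906156, 64 loops of 217 to 348 kb were lost, 25 of them with an end in TMEM132E, and 175 of the 481 listed loops inside the region were gained. The other 9 of the 10 lost regions with most loops held 0 gained loops. On chromosome 5 at 177375284 to 177468720, 25 lost loops had left ends at the coagulation factor XII gene F12 (12 loops) and the renal phosphate transporter gene SLC34A1 (10 loops), and right ends at PRR7 (18 loops) and the actin-binding protein gene DBN1 (11 loops). GRIK3, a kainate receptor gene on chromosome 1, had 23 lost loops of 435 to 487 kb (36551330 to 37038668), and CYRIA, a regulator of RAC1 signalling on chromosome 2, had 22 (16613430 to 16758754). Further lost regions had ends at NTMT1 and C9orf50 on chromosome 9 (129307270 to 129619555, 19 loops), PHACTR3 on chromosome 20 (59567834 to 59755222, 18 loops) and ERGIC1 and NEURL1B on chromosome 5 (172685661 to 172961281, 17 loops). The last 3 had 15 lost loops each, at SLCO3A1 on chromosome 15 (92086270 to 92238920), at SSR4 on chromosome X (153789497 to 153963447) and on chromosome 16 (681011 to 819840). In the chromosome 16 region 12 of the 15 had an end at FBXL16.

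**Figure D3:**
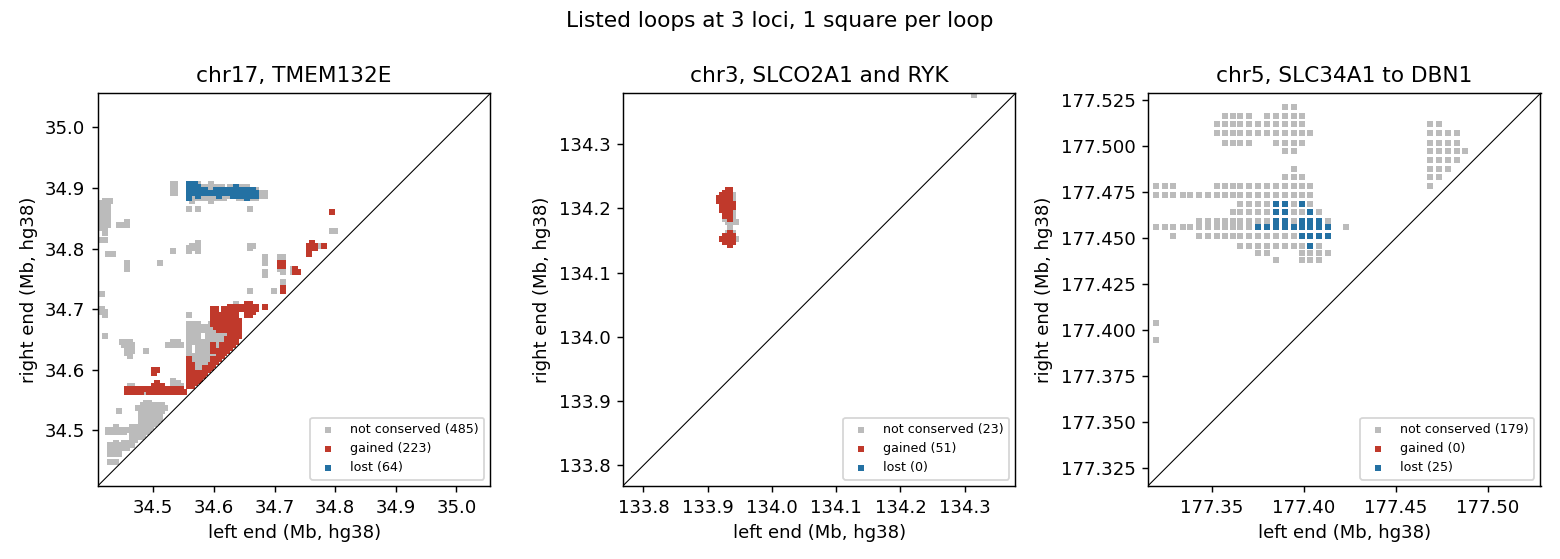
Listed loops at 3 loci, with the left end on the horizontal axis and the right end on the vertical axis, in Mb of hg38. Each square is 1 loop, coloured by class, and the line marks equal positions. On chromosome 17, 199 of the gained loops form a block near the diagonal below a stripe of 64 lost loops, whereas each of the loci on chromosomes 3 and 5 holds 1 of these classes, 51 gained and 25 lost.

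In the authors' deposited table, protein-coding genes lay at the ends of gained, lost and not conserved loops at shares whose intervals overlapped. At least 1 end overlapped a gene in 75.0% (70.0 to 79.8%) of gained, 78.8% (66.9 to 89.9%) of lost and 76.8% (74.5 to 78.9%) of not conserved loops. Both ends overlapped a gene in 30.4% (25.9 to 35.7%) of gained and 36.2% (33.7 to 38.9%) of not conserved loops. These intervals overlapped, but each share lay outside the other's interval. With ends read 10 kb inward the shares were 35.3% (30.4 to 40.8%) and 40.4% (37.7 to 43.1%). No interval of the difference was made, so the overlap does not show equal shares. In all, 1260 genes had a gained loop end, 183 a lost one and 10 both, where independent lists would share 23.3 of the 9909 genes at any listed end. Among the 10 were TMEM132E, GNAS, RUNX1, RNF213, ZNF346, ASIC2, GSN, ITPR1 and RPTOR. Genes with many gained loops and no lost ones included the oestrogen receptor gene ESR1 (44 of 167 listed loops) and its neighbour SYNE1 (45 of 164), a nuclear envelope protein gene. The bodies of ESR1 and SYNE1 overlap, and a loop can count at both. Other such genes were HIF1A, encoding a hypoxia-induced transcription factor (28 of 78), KSR2 (46 of 335) and the epithelial transcription factor gene ELF5 (18 of 94). RUNX1, a haematopoietic transcription factor gene, had 26 gained and 2 lost of 111.

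At the deleted gene itself, ORC2 (chromosome 2, 200908977 to 200963660), 77 listed loops had an end, and none of them was classed as gained or lost. They were classed as not conserved, which is not taken to mean unchanged. The genome-wide share would give 1.51 gained loops there, and 0 of 77 allows a share of up to 3.90%, so gained loops at the genome-wide share were not detectable. None of the 17 genes of the origin recognition complex and origin licensing (ORC1 to ORC6, CDC6, CDT1, MCM genes and others) had a gained or lost loop end, although 9 of them had listed ends. This 0 lay at the 14.8th percentile of matched random lists. Among 12 replisome and origin firing genes with listed ends, GINS1, a subunit of the replicative helicase, had 1 gained loop and POLE, the leading-strand polymerase gene, had 3 lost of 155.

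Of 16 fixed lists, 11 had at least 1 member with a gained end and 4 had a member with a lost end. Clustered protocadherins, cell-adhesion genes arranged in arrays on chromosome 5, had 15 of 46 members at gained ends against a mean of 8.60 in random lists (99.1th percentile). The gene bodies of this array overlap, and only 4 distinct gained loops, of 180 to 348 kb, stood behind the 15 genes. HOX genes, the homeotic transcription factors, had 6 of 37 members at gained ends, all in the HOXB cluster on chromosome 17, where 10 of 53 listed loops at HOXB7 and 10 of 53 at HOXB8 were gained. The HOX count was close to the random mean of 5.51 (60.7th percentile). With random lists matched on gene length it lay at the 98.8th percentile, but the 6 neighbouring genes share 22 distinct gained loops in 3 regions, which random lists of separate genes do not model. Neuronal genes had 4 of 13 members at gained ends (LSAMP, KCNIP4, GRM5 and SYT1), at the 92.3th percentile and, with random lists matched on gene length, at the 62.6th. RBFOX1 had 1 lost loop. Mesenchymal and fibroblast genes had 2 members at lost ends, the collagen gene COL3A1 and the growth factor receptor gene PDGFRA, each with 1 lost loop (99.4th percentile), and COL5A2 with 1 gained loop. Of the 32 list counts set against random lists, 2 fell in the top 2.5%, those of the protocadherins for gained and the mesenchymal genes for lost ends. Chance nominally gives 0.8 for lists of separate genes.

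The other lists lay inside the range of random lists. Intestinal epithelial genes had 1 of 16 members at a gained end, SOX9 (7 of 54 listed loops), a transcription factor of intestinal crypts. Cell cycle regulators had 1 of 10, MYC (3 of 127 listed loops), and cohesin, CTCF and condensin genes had 1 of 10, the cohesin subunit gene STAG1 (2 of 15). Ribosomal protein genes had 5 of 46 members at gained ends and RPL10 and RPL26L1 at lost ends. Olfactory receptors had 3 of 62 and ZNF genes of chromosome 19 had 1 of 32 members at gained ends. No Polycomb and heterochromatin gene (11 with listed ends), immune gene (11), interferon response gene (11) or replication-dependent histone gene (10) had a gained or lost end.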

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

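Counts and lengths on autosomes only were planned before the data were examined, and the other alternatives were chosen after seeing the data. Of 33 alternatives, 27 left a count within 1.5 times its value, a share within its Wilson interval or a median within its resampling interval. The other 6 went past these limits. Leaving out the 10 windows densest in lost loops, which held 48.0% of them, lowers their count and raises the gained share by construction. No other cause was tested. Without the densest windows the lost loops fell to 285, and gained loops made up 94.2% of gained and lost loops, against 92.1% on autosomes only, which lies inside the wider resampling interval of 87.8 to 93.8%. Counted by region, the median length of not conserved loops was 219 kb. Without loops past 150 Mb, a position chosen after the lost loops were seen there, the lost share on chromosome X was 0.984%. Matching random lists on gene length put 2 lists in place of 1 in the top 2.5% for gained ends, HOX among them. Gained loops numbered 4537 to 5484 under the alternatives, and the gained median was 298 to 339 kb. The share gained above 1 Mb was 9.94% without the 1 Mb window that held most such loops. It stayed at 11.0% on autosomes only and without the densest windows. Neither setting removed a loop of that length, so neither could move it. Settings on fold change, loop strength and a pseudocount were not run because the list holds no strengths, and those on compartments and on scores in gene lists were not run because the compartment columns match no sample label. The return of loops in rescued cells could not be computed either. No paired analysis was possible because each group has 1 library and the loop list carries no sample values. Depth is unknown, so its effect on the classes could not be examined.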

Other observations

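The tests in this part were chosen after the results were seen, except the one on isolated regions. Some genes had most or all of their listed loops gained. Among 6114 genes with at least 10 listed loops, 39 had 50% or more of them gained and 0 had 50% or more lost. The gained class held 5493 loops and the lost class 548, so fewer genes with mostly lost loops would be found on that account alone. Loops at a gene are often neighbours and are not independent. All 20 loops at MTAP, a methionine salvage gene, and all 11 at CDC73, a transcription elongation factor gene, were gained. So were 24 of 27 at VCAN, encoding the matrix proteoglycan versican, 10 of 11 at the lymphangiogenic growth factor gene VEGFC, 23 of 32 at the autophagy gene ATG5 and 10 of 16 at the adaptor gene GRB2. The chromatin organiser gene SATB1 had 6 of 11.

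Some genes with many listed loops had few in the gained and lost classes. ASIC2 on chromosome 17 had 2190 listed loops with 16 gained and 3 lost, and AJAP1 on chromosome 1 had 1480 with none of either.

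Gained loops were longer than loops that were not conserved. Without the 10 windows holding most gained loops, the gained median rose from 300 kb to 340 kb (308 to 371 kb). The median of loops that were not conserved was then 234 kb. Those 10 windows therefore do not account for the difference, but they were chosen by number of loops and not by length. No median was computed without the windows holding most long gained loops, so a few such windows stay open as an explanation. Sparse contacts at long distance may produce scattered calls. Single-loop regions made up 30.7% of 313 gained regions over 500 kb and 36.5% of 861 regions of 100 to 500 kb. The difference was -5.80 percentage points (-11.9 to 0.27), with an interval from simulated binomial counts that treats regions as independent. That interval includes 0, so this explanation stays open, and a biological difference between the samples was not tested.

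On chromosome 17 a block of gained loops overlapped a region of longer lost loops at TMEM132E. All 64 lost loops of the region (100%) crossed the right edge of the gained block, at 34708424, but the extent of the region and the lengths of its loops fix that outcome. It therefore decides nothing about a change of contacts at that edge, such as a breakpoint or a new boundary, which stays open. Of 205 listed loops with 1 end in the block, 64 were lost and 0 gained. More copies of the segment could raise such contacts, but whether contacts were corrected for coverage is not stated, which keeps that explanation open.

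Lost loops were over-represented on chromosome X. Fewer contacts along the whole chromosome would spread them as the listed loops are. Past 150 Mb lay 71.4% of the 14 lost regions (10 regions, Wilson 45.4 to 88.3%), 23.8% of the other regions and 44.4% of the listed loops of X, but that position was chosen after the lost loops were seen there, so a whole-chromosome cause stays open. Short of 150 Mb the lost share was 0.984% (0.0856 to 1.93%), from 4 regions, against 0.170% on the autosomes, and this part stays open too. A local change near the end of the long arm, in copy number or in chromatin, was not tested.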
